A study of Mus musculus with 6 samples.

How the data were processed

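RNA-seq libraries came from primary articular chondrocytes of ICR mice at postnatal day 4, 3 cultured without and 3 with semaphorin 4D, per the labels. Total RNA was used, per the labels' protocols. The dose and duration of stimulation, the composition of the control medium, the source of the protein and the sequencing layout were not given in the sources used here. The labels call the libraries replicates 1 to 3 of each group and do not say whether these were separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. The deposited values are FPKM (fragments scaled to transcript length and to mapped fragments), made by the authors with TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cufflinks 2.2.1 on the mouse build mm10, per the submitters' processing notes, which give no role or order for each tool. The gene annotation, the strand setting, any filter and any scaling across libraries were not given in the sources used here. Without the strand setting, reads of overlapping sense and antisense genes cannot be told apart, and values of near-identical copies, such as the class I histocompatibility genes, are uncertain.

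The file held 1 column per library for 24346 gene symbols, and no column outside the series. FPKM columns summed to 493457 ± 711 (mean ± SD, n = 3) in the control and 522490 ± 4466 in the Sema4D libraries, of which Saa3 alone took 1.59% to 1.69% in the Sema4D libraries. FPKM are not counts, so no count test was run. Depth was estimated from 1681 genes with 1 transcript longer than 2000 nucleotides, whose low FPKM values fall on steps of whole fragments: 76.5% to 84.8% of low values lay within 0.15 of a whole number. This gave 1.25e+07 to 1.66e+07 fragments per library, so that 1 fragment on 1 kilobase was worth 0.0604 to 0.0798 FPKM, and the share of whole values was too low to recover counts. In each pair of libraries 0.112% to 0.293% of the tested genes had the same value, so no library was a second deposit of identical values, and all 6 libraries were counted. An exact 0 can be a failed estimate: Rpl26, a ribosomal protein gene every cell uses, was at 0 in Sema4D replicate 1 and at 3.90 to 20.5 FPKM in the other libraries. Genes with a 0 in any library are therefore given per library.

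Values were taken as deposited and transformed to log2(FPKM + 1). Fold changes are on that scale, which understates the change of genes with low FPKM. The 11603 genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 (lmFit and eBayes with a trend, two-sided) in R 4.3.3, without a replicate block, with Benjamini-Hochberg adjustment and an adjusted p under 0.05 as the threshold. The other 12743 symbols were under the filter. Figures and depth estimates used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene positions are those of whole genes in the RefSeq annotation of GRCm38.p6, the assembly of mm10, where the genes given with a position are protein-coding, and 23143 of the 24346 symbols matched it. Transcript lengths came from GENCODE M21.

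Before the data were examined, 30 gene lists, the alternatives and the rule for named genes were written from textbook knowledge. Lists covered inflammatory pathways, cartilage matrix and its regulators, proteases and their inhibitors, signalling pathways, metabolism, stress, cell cycle, histones, mitochondrially encoded genes and markers of other cell types (fibroblasts, osteoblasts, macrophages and osteoclasts, endothelium, muscle, neutrophils and erythroid cells, neural and glial cells). The 23 lists with at least 5 tested members were tested with camera in limma with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes, while fry asks whether its members move 1 way on balance and compares it with no other gene. No symbol of the mitochondrially encoded list was matched in the file, so that list was void. Genes eligible for naming were the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, passing over predicted genes, small RNAs and pseudogenes, the 3 members of each list with the smallest p, and 21 genes fixed by name. Other list members are named in the report where a count was small, and were chosen after their values were seen, as were 10 further lists used in the closing section.

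The fits and list tests were tested on simulated data for the comparison of Sema4D with control, with 11603 genes, 200 of them changed, and each gene's own mean and spread. At a true change of 1.25-fold 40% of the changed genes were recovered, at 1.5-fold 72%, at 2-fold 92% and at 4-fold 98%, and 0.0441% of unchanged genes were called. A simulated list of 20 genes raised 1.25-fold passed camera, and 0 of 20 unchanged lists did. The simulated genes varied independently of each other, so these lists could not show how camera behaves when members vary together. Far fewer genes were changed in the simulation than the 46.7% of tested genes called in the data. The alternatives tried were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, no trend in the variance prior, a replicate block, array weights, each library left out in turn, limma treat against 1.5-fold, the other set tests and, chosen after seeing the data, small RNA genes left out.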

Results

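RNA-seq was performed on primary articular chondrocytes, the cells that make and maintain joint cartilage, taken from ICR mice at postnatal day 4. The cells were cultured with or without semaphorin 4D (Sema4D), a ligand of the plexin-B receptors. There were 3 control and 3 Sema4D libraries, and expression was read as FPKM for 24346 gene symbols. Depth was estimated from the steps of low FPKM values at 1.25e+07, 1.6e+07 and 1.55e+07 fragments in control replicates 1, 2 and 3 and at 1.66e+07, 1.54e+07 and 1.4e+07 in Sema4D replicates 1, 2 and 3. The first principal component of the tested genes held 75.4% of the variance and separated the groups. Pearson's r across genes, which are not independent replicates, was 0.983 to 0.991 within groups and 0.935 to 0.942 between them.

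The comparison asked which transcripts differ in chondrocytes stimulated with Sema4D. Saa3, an acute phase serum amyloid A gene (chromosome 7, 46711998 to 46719615 in mm10), rose from 0.799 ± 0.205 FPKM in control to 8633 ± 305 FPKM in Sema4D libraries (mean ± SD, n = 3 per group, in this order throughout; log2 fold change 12.23, SE 0.076, limma adjusted p = 3.43e-12). Mmp3, which encodes the matrix-degrading protease stromelysin (chromosome 9, 7445822 to 7455975), rose from 0.412 ± 0.0665 to 1165 ± 16.7 FPKM (9.69, SE 0.040, adjusted p = 4.02e-13). The neutrophil chemoattractants Cxcl1 (chromosome 5, 90891245 to 90893121) and Cxcl5 rose from 0.719 ± 0.152 to 1058 ± 48.3 FPKM and from 1.26 ± 0.122 to 899 ± 32.6 FPKM, and the monocyte chemoattractants Ccl2 (chromosome 11, 82035577 to 82037452) and Ccl7 from 1.7 ± 0.078 to 1556 ± 59.8 FPKM and from 2.03 ± 0.109 to 554 ± 14.2 FPKM. Acan, the gene of the main cartilage proteoglycan (chromosome 7, 79053226 to 79115099), fell from 566 ± 10.7 to 341 ± 8.27 FPKM (-0.73, SE 0.028, adjusted p = 2.07e-07), and Sox9, the transcription factor needed for chondrocyte identity (chromosome 11, 112782210 to 112787757), fell from 66.2 ± 3.47 to 35.8 ± 1.9 FPKM (-0.87, SE 0.050, adjusted p = 2.32e-06).

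The naming rule passed over predicted genes, small RNAs and pseudogenes. The other genes among its 10 largest rises were Nos2, Ccl5, Lcn2 and Ccl20. Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960226), was listed at 0, 0 and 0.0157 FPKM in the control libraries and 286, 269 and 255 FPKM in the Sema4D libraries (limma adjusted p = 2.93e-12). Ccl20, the ligand of the chemokine receptor CCR6, was listed at 0, 0 and 0 FPKM in the control libraries and 105, 108 and 91.9 FPKM in the Sema4D libraries (adjusted p = 3.41e-11). Lcn2, which binds bacterial iron carriers (chromosome 2, 32384637 to 32387739), rose from 16.2 ± 1.41 to 2112 ± 27.4 FPKM (6.94) and the chemokine Ccl5 from 0.802 ± 0.115 to 411 ± 13.6 FPKM (7.84). Under the same rule the 10 largest falls were smaller. Hpgd, whose enzyme inactivates prostaglandins (chromosome 8, 56294552 to 56321046), fell from 10.6 ± 0.493 to 1.36 ± 0.163 FPKM (-2.30, SE 0.068, adjusted p = 4.08e-08). Lrrc17 fell from 48.8 to 11.1 FPKM (-2.05), the water channel gene Aqp1 from 109.7 to 30.5 FPKM (-1.81) and the secreted Wnt modulator Sfrp2 from 318 to 90.9 FPKM (-1.80). Ndnf (-1.79), the neutral sphingomyelinase gene Smpd3 (-1.78), the BMP-responsive gene Id1 (-1.74), the small proteoglycan gene Aspn (-1.73), Angptl1 (-1.72) and the homeobox gene Meox1 (-1.69) completed the falls.

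Of 11603 genes tested with limma, 2841 were higher and 2581 lower with Sema4D at an adjusted p under 0.05, 46.7% of those tested. Of the higher genes, 773 changed by over 1.5-fold, 393 by over 2-fold and 123 by over 4-fold. Of the lower genes, 431 changed by over 1.5-fold, 109 by over 2-fold and 4 by over 4-fold. All these folds are on the log2(FPKM + 1) scale. On that scale the 4 were Hpgd, Lrrc17 and, named after their values were seen, the small nucleolar RNA genes Snora34 and Snora81. By the ratio of mean FPKM, Ndnf (6.02-fold) and Smpd3 (4.87-fold) also fell by over 4-fold. Snora34 was listed at 127, 98.4 and 205 FPKM in the control libraries and 0, 0 and 0 FPKM in the Sema4D libraries, and Snora81 at 9.83, 15.2 and 15.8 FPKM in the control libraries and 0, 0 and 0 FPKM in the Sema4D libraries. Such values are unsteady: of 53 tested small RNA genes, 39 were at 0 in a library and above 5 FPKM in another of the same group. The groups did not overlap for 6568 tested genes, against 10% expected by chance with 3 libraries against 3. Against a minimum change of 1.5-fold (limma treat), 513 genes were higher and 199 lower. Of the calls, 52.4% were higher, and after quantile normalization 38.8% were (2167 higher and 3415 lower). Of 23 fixed gene lists with enough tested members, 16 differed from the other genes by limma's camera test with a preset correlation, and 5 did with an estimated correlation. Those 5 were the NF-kappaB, acute phase, glycolysis and hypoxia, chemokine and immediate early lists.

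**Figure D1:**
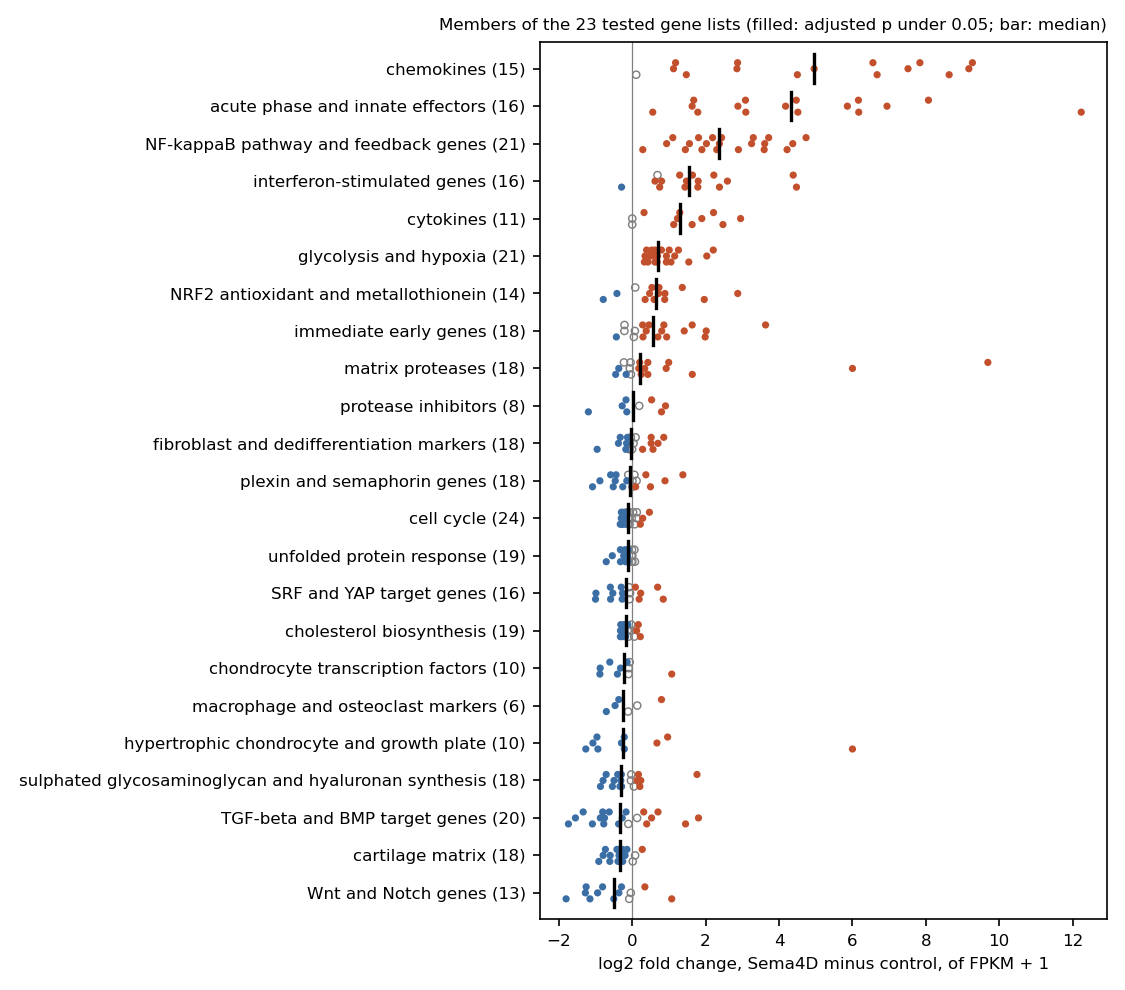
The plot shows log2 fold changes (x axis, Sema4D minus control, on the log2(FPKM + 1) scale) of the tested members of each of the 23 tested gene lists (y axis, number of tested members in parentheses), with members past an adjusted p of 0.05 filled in red (higher) or blue (lower) and a black bar at the median. All 21 NF-kappaB, 16 acute phase and 21 glycolysis and hypoxia members lie to the right of 0, and 15 of 18 cartilage matrix members are filled in blue.

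Inflammatory groups rose together. All 21 tested NF-kappaB pathway and feedback genes rose (median log2 fold change 2.38, camera adjusted p = 1.57e-18, or 0.0152 with an estimated correlation). They included the adhesion receptor gene Icam1 (from 9.67 ± 0.244 to 284 ± 13.6 FPKM) and the inhibitor gene Nfkbia (from 9.13 ± 0.44 to 123 ± 2.76 FPKM). Nfkbiz (from 2.46 ± 0.278 to 70.7 ± 2.26 FPKM) and the RNase gene Zc3h12a (from 1.91 ± 0.047 to 53.2 ± 2.17 FPKM) were also among them. Cebpd and Cebpb, transcription factors of the acute phase response, rose from 3.29 ± 0.691 to 55.2 ± 5.92 FPKM and from 16.2 ± 0.42 to 84.2 ± 4.01 FPKM. All 16 tested acute phase and innate effector genes rose (median 4.33, camera adjusted p = 3.53e-17, or 0.0152 with an estimated correlation). Among them were the metalloreductase gene Steap4 (from 0.831 ± 0.070 to 130.3 ± 3.24 FPKM) and the prostaglandin synthase gene Ptgs2 (from 1.31 ± 0.255 to 6.14 ± 0.0956 FPKM, log2 fold change 1.64, limma adjusted p = 1.32e-06). Of 15 chemokine genes, 14 rose (median 4.96, camera adjusted p = 1.17e-15, or 0.033 with an estimated correlation). The exception was Cxcl14 (0.11, limma adjusted p = 0.256). The chemokine median was 7.51 with a pseudocount of 0.1 and 2.86 over 20 genes with no filter on low values, where 17 rose.

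Of 11 cytokine genes, 9 rose (median 1.30, camera adjusted p = 4.9e-06; adjusted p = 0.0729 with an estimated correlation). Il6 was listed at 0, 0 and 0 FPKM in the control libraries and 5.78, 8.04 and 6.61 FPKM in the Sema4D libraries (limma adjusted p = 1.43e-07). Csf1, which sustains macrophages, rose from 74.7 ± 1.67 to 185 ± 3.95 FPKM, and Tnfsf11, which encodes the osteoclast differentiation factor RANKL, from 0.285 ± 0.0719 to 6.15 ± 0.577 FPKM. The other 2 cytokine genes did not pass the threshold. With a mean FPKM of at least 5, 4 of 6 cytokine genes rose (median 0.73). Adjusted over the list alone, the counts of the NF-kappaB, acute phase, chemokine and cytokine lists were the same. Of 6 tested macrophage and osteoclast markers, the endotoxin co-receptor gene Cd14 rose (0.80, from 1.84 ± 0.239 to 3.95 ± 0.448 FPKM). Among the 3 of these markers that fell were Lyz2 (-0.46, from 22.4 ± 3.55 to 15.9 ± 1.27 FPKM) and Tyrobp (-0.70), and 2 were not past the threshold, with the same counts adjusted over the list alone (list adjusted p = 0.469).

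**Figure D2:**
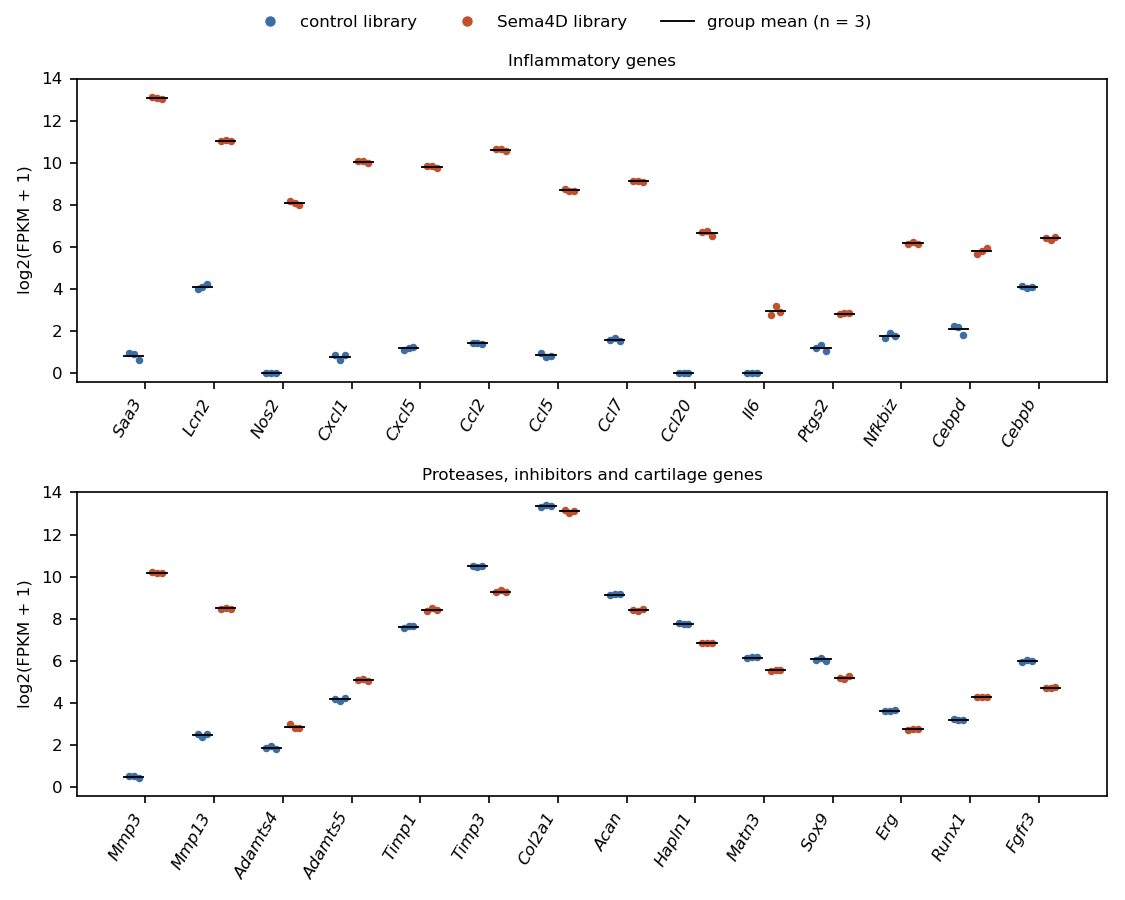
Points are the log2(FPKM + 1) values (y axis) of the 3 control (blue) and 3 Sema4D (red) libraries for 14 inflammatory genes in the upper panel and 14 protease, inhibitor and cartilage genes in the lower panel, with black lines at the group means. Saa3 lies above Lcn2 and every other plotted gene of the upper panel in the Sema4D libraries, while Acan, Hapln1, Matn3 and Sox9 lie lower in the Sema4D than in the control libraries.

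Of 16 interferon-stimulated genes, 14 rose (median 1.56, camera adjusted p = 3.09e-06; adjusted p = 0.259 with an estimated correlation), and 15 rose adjusted over the list alone. The guanylate-binding protein gene Gbp2 rose from 0.854 ± 0.144 to 40.3 ± 2.71 FPKM and the transcription factor gene Irf1 from 7.38 ± 0.46 to 38.2 ± 1.08 FPKM. Gbp5 was listed at 0, 0.0407 and 0 FPKM in the control libraries and 20.4, 21.2 and 19.1 FPKM in the Sema4D libraries (limma adjusted p = 4.04e-10). Ifit2 fell (-0.29, adjusted p = 0.00371), and 1 gene did not pass the threshold. In 15 of the 16 genes Sema4D replicate 2 had the highest value of the Sema4D libraries, with a median excess of 0.63 on the log2 scale over the mean of the others. Without that library 14 genes still rose, 1 fell, and the median was 1.23.

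**Figure D3:**
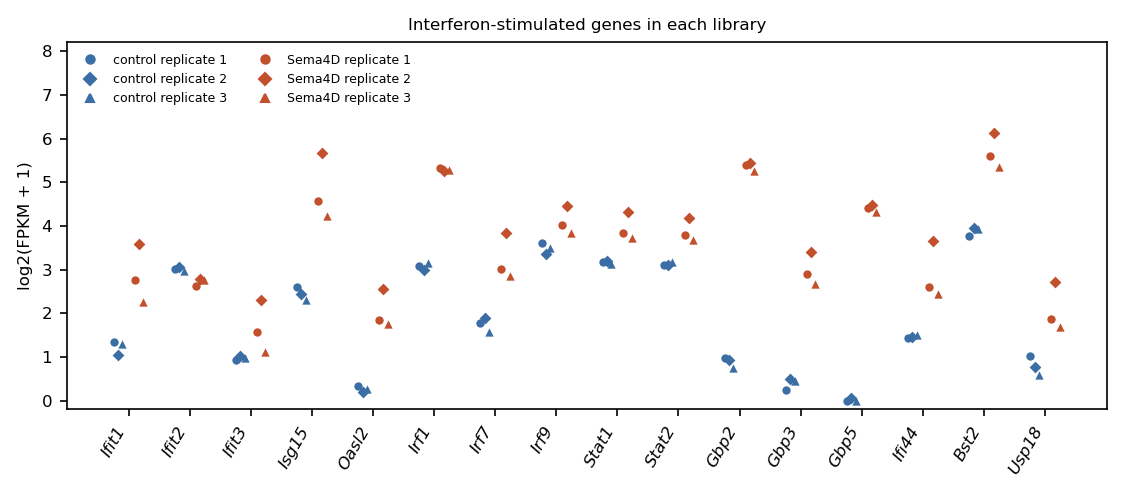
Points are the log2(FPKM + 1) values (y axis) of the 16 tested interferon-stimulated genes (x axis) in each control (blue) and Sema4D (red) library, with circles for replicate 1, diamonds for replicate 2 and triangles for replicate 3. The diamond of Sema4D replicate 2 is the highest Sema4D point in 15 genes, with an excess of 1.27 for Isg15 and of -0.05 for Irf1.

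Immediate early genes rose in 13 of 18 cases and fell in 1 (median 0.58, or 0.34 with no filter on low values, camera adjusted p = 2.02e-05, or 0.0384 with an estimated correlation). The largest of the named rises were those of Ier3 (from 14.6 ± 1.34 to 193 ± 12.6 FPKM), Junb (from 11.1 ± 0.172 to 48.2 ± 3.1 FPKM) and Phlda1 (from 7.19 ± 0.284 to 24.5 ± 0.831 FPKM), while Egr1 fell (-0.43, adjusted p = 8.91e-05), and without control replicate 1 the falls were 2. The other 4 did not pass the threshold. All 21 genes of glycolysis and the hypoxia response rose (median 0.69, camera adjusted p = 5.71e-15, or 0.0152 with an estimated correlation). They included the vasodilator gene Adm (from 21.2 ± 0.726 to 102 ± 2.88 FPKM), Pfkfb3, which drives glycolytic flux (from 13.8 ± 0.183 to 42.2 ± 0.519 FPKM), and Ndrg1 (from 72.6 ± 0.521 to 147 ± 1.79 FPKM). Of 14 NRF2 antioxidant and metallothionein genes, 11 rose and 2 fell (median 0.66, adjusted p = 2.02e-05; adjusted p = 0.0729 with an estimated correlation). The metal-binding metallothionein genes Mt1 and Mt2 rose from 285 ± 2.72 to 1118 ± 29.8 FPKM and from 275 ± 17.3 to 2028 ± 111 FPKM, and the autophagy receptor gene Sqstm1 from 257 ± 3.54 to 479 ± 1.14 FPKM. Nqo1 (-0.41) and Gsta4 (-0.79) were the falls of that list. Adjusted over the list alone, the counts of the immediate early, glycolysis and NRF2 lists were the same.

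Cartilage genes were lower with Sema4D. Of 18 cartilage matrix genes, 15 fell and 1 rose (median -0.34, camera adjusted p = 2.62e-06; adjusted p = 0.0932 with an estimated correlation). The link protein gene Hapln1 fell from 216 ± 3.58 to 114 ± 0.859 FPKM (-0.91) and the matrilin gene Matn3 from 70.5 ± 0.789 to 45.9 ± 0.711 FPKM (-0.61). Col2a1, which encodes the main cartilage collagen (chromosome 15, 97975602 to 98004724), fell from 10506 ± 472 to 8796 ± 372 FPKM (-0.26, SE 0.043, limma adjusted p = 0.00144). After quantile normalization its change was -0.07 (adjusted p = 0.459, within a range of 0.000538 to 0.459 over the alternatives). Vit rose (0.28, adjusted p = 0.0136, 0.0527 without Sema4D replicate 1, within a range of 0.00784 to 0.0527 over the alternatives). Of 10 chondrocyte transcription factor genes, 6 fell and 1 rose (median -0.23, adjusted p = 0.0119; adjusted p = 0.0932 with an estimated correlation). Erg, of the ETS family, fell from 11.3 ± 0.248 to 5.7 ± 0.111 FPKM (-0.88), and Runx1 rose from 8.22 ± 0.301 to 18.5 ± 0.268 FPKM (1.08). The other 3 did not pass.

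Of 18 genes of sulphated glycosaminoglycan and hyaluronan synthesis, 10 fell and 5 rose (median -0.29, or -0.16 with no filter on low values, camera adjusted p = 0.0388; adjusted p = 0.123 with an estimated correlation). The sulphate transporter gene Slc26a2 fell from 39.8 ± 0.744 to 21.4 ± 0.258 FPKM (-0.86) and Papss2, which makes the sulphate donor, from 177 ± 3.47 to 108 ± 1.65 FPKM (-0.71). The hyaluronan receptor gene Cd44 rose from 18.1 ± 0.193 to 63.9 ± 3.52 FPKM (1.77), and the chondroitin synthase gene Chsy1 (0.21) and Ugdh (0.24) also rose. The 5 rises became 3 without Sema4D replicate 2 or 3 or after quantile normalization. That list's call was lost with no filter on low values (adjusted p = 0.0515), a mean FPKM of at least 5 (0.0677), quantile normalization (0.0759) or Sema4D replicate 1 left out (0.0553), within a range of 0.0275 to 0.123 over the alternatives by camera. Adjusted over the list alone, the counts of the cartilage matrix, chondrocyte transcription factor and glycosaminoglycan lists were the same.

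Of 18 matrix protease genes, 11 rose and 3 fell (median 0.23, or 0.13 after quantile normalization, camera adjusted p = 0.00562; adjusted p = 0.0826 with an estimated correlation), and 11 rose and 4 fell adjusted over the list alone. The collagenase gene Mmp13 (chromosome 9, 7272514 to 7283333) rose from 4.62 ± 0.363 to 359 ± 5.17 FPKM (6.0, SE 0.048, limma adjusted p = 1.29e-11). The aggrecanase genes Adamts4 (chromosome 1, 171250129 to 171262267) and Adamts5 (chromosome 16, 85858157 to 85901125) rose from 2.65 ± 0.151 to 6.29 ± 0.56 FPKM (1.0, adjusted p = 8.12e-06) and from 17 ± 0.671 to 33.3 ± 1.18 FPKM (0.93, adjusted p = 5.71e-07). The falls were those of Adamts12 (-0.45), Htra1 (-0.16) and Plat (-0.36). Of 8 protease inhibitor genes, 3 rose and 4 fell, and 4 rose and 4 fell adjusted over the list alone (list adjusted p = 0.962, median 0.03, or -0.14 with a mean FPKM of at least 5, -0.03 with no filter on low values and -0.04 after quantile normalization). Timp1, an inhibitor of matrix metalloproteinases, rose from 198 ± 6.47 to 345 ± 15.3 FPKM (0.80), and Timp3, which also blocks aggrecanases, fell from 1435 ± 39.7 to 628 ± 25.1 FPKM (-1.19). Serpine2 (0.91) rose, and Timp2 (-0.14), Reck (-0.17) and Cst3 (-0.27) fell.

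Of 10 tested hypertrophic chondrocyte and growth plate genes, 3 rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.268). The 7 falls became 4 without control replicate 2, 5 without control replicate 1 or 3, without Sema4D replicate 1 or 2 or with a replicate block, and 6 without Sema4D replicate 3, with a pseudocount of 0.1 or with no filter on low values. With a mean FPKM of at least 5, 2 of 5 tested members fell and the median was 0.68. Fgfr3, which restrains chondrocyte growth, fell from 62.9 ± 1.62 to 25.7 ± 0.626 FPKM (-1.26). Spp1 rose from 107 ± 3.75 to 211 ± 6.38 FPKM (0.97), and the other rises were Mmp13 and the angiogenic factor gene Vegfa (0.68). The list's median was -0.25 and its mean 0.27, and camera put it down while fry, limma's rotation test, put it up. Mmp13, which is also a matrix protease, stood at 6.0 in it. Alpl, which this list shared with the osteoblast markers, passed narrowly (-0.21, limma adjusted p = 0.049). Its adjusted p was 0.0597, 0.0797 and 0.137 without control replicate 1, 2 or 3 and 0.139 and 0.0935 without Sema4D replicate 1 or 2. It also missed the threshold with a pseudocount of 0.1 (0.0517) and with no filter (0.0679), within a range of 0.0243 to 0.139 over the alternatives.

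Of 20 TGF-beta and BMP target genes, 12 fell and 6 rose (median -0.32, or -0.75 with a mean FPKM of at least 5, camera adjusted p = 0.0221; adjusted p = 0.0988 with an estimated correlation). Gdf10 fell from 32.7 ± 0.874 to 10.6 ± 0.724 FPKM (-1.54) and the BMP antagonist gene Chrdl1 from 42.7 ± 0.382 to 19.7 ± 0.988 FPKM (-1.08), while Ltbp2, which encodes a latent TGF-beta binding protein, rose from 35.2 ± 1.46 to 98.3 ± 2.37 FPKM (1.46). The list was not past the threshold after quantile normalization (adjusted p = 0.0911, within a range of 0.00209 to 0.0988 over the alternatives by camera). Of 13 Wnt and Notch genes, 9 fell and 2 rose (median -0.50, adjusted p = 0.0016; adjusted p = 0.0932 with an estimated correlation). The secreted Wnt inhibitor gene Frzb fell from 37.5 ± 2.42 to 14.9 ± 1.04 FPKM (-1.27) and Dkk3 from 154 ± 2.27 to 69.1 ± 2.1 FPKM (-1.15). The Wnt and Notch median was -0.22 with no filter on low values (9 of 20 fell) and -1.21 with a mean FPKM of at least 5 (4 of 4 fell). The rises were the Notch ligand gene Jag1 (1.08) and Lef1 (0.35). Adjusted over the list alone, the counts of both lists were the same.

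Of 18 plexin and semaphorin genes, 5 rose and 8 fell (camera adjusted p = 0.353). Among the Sema4D receptor genes, Plxnb1 fell from 13.2 ± 0.27 to 8.91 ± 0.325 FPKM (-0.51, SE 0.043, limma adjusted p = 2.26e-05) and Plxnb2 from 74.6 ± 2.98 to 67.4 ± 0.0171 FPKM (-0.14, SE 0.034, adjusted p = 0.00867). Cd72, the lymphocyte receptor gene, was at 1.22 ± 0.152 FPKM in control and 1.23 ± 0.101 FPKM in Sema4D libraries (0.01, adjusted p = 0.952). The transcript of Sema4d itself was under the expression filter, at 0.628 ± 0.16 FPKM in control and 0.671 ± 0.0732 FPKM in Sema4D libraries. Plxnd1 (from 1.49 ± 0.142 to 5.48 ± 0.339 FPKM, 1.38) and the co-receptor gene Nrp2 (from 79.7 ± 0.843 to 149 ± 5.05 FPKM, 0.90) rose, and the repulsive guidance cue gene Sema3a fell from 14.9 ± 0.37 to 6.53 ± 0.264 FPKM (-1.08). Of 16 SRF and YAP target genes, 5 rose and 8 fell (adjusted p = 0.0876). Ctgf and Cyr61, matricellular genes controlled by YAP, fell from 521 ± 1.83 to 263 ± 8.8 FPKM and from 110.3 ± 2.11 to 54.8 ± 1.72 FPKM, and the smooth muscle actin gene Acta2 rose from 33.2 ± 1.55 to 60.6 ± 1.49 FPKM. Adjusted over the list alone, the counts of both lists were the same.

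Of 19 unfolded protein response genes, 12 fell and none rose (median -0.12, or -0.23 after quantile normalization, camera adjusted p = 0.0016; adjusted p = 0.0729 with an estimated correlation), with Herpud1 (-0.54), Chac1 (-0.70) and Atf5 (-0.32) among them. Of 19 cholesterol biosynthesis genes, 11 fell and 3 rose (median -0.18, adjusted p = 0.0108; adjusted p = 0.437 with an estimated correlation). Among the falls were those of Hmgcs1 (-0.31) and Idi1 (-0.32). The 3 rises became 1 without control replicate 1, control replicate 2 or Sema4D replicate 2, and none of the 19 rose after quantile normalization. Of 24 cell cycle genes, 3 rose and 11 fell, and 12 fell adjusted over the list alone (adjusted p = 0.0554, 0.0499 without control replicate 1, 0.0413 without control replicate 2 and 0.0228 without Sema4D replicate 2, within a range of 0.0206 to 0.428 over the alternatives by camera). The replication genes Mcm3 (0.47) and Pcna (0.29) rose, and the mitotic cyclin gene Ccnb2 fell (-0.29). The counts of the unfolded protein response and cholesterol lists were the same adjusted over the list alone.

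For markers of other cell types, ranges of adjusted p are over the alternatives. Of 18 fibroblast and dedifferentiation markers, 6 rose and 6 fell, and 7 rose adjusted over the list alone (camera adjusted p = 0.779, median -0.02, mean 0.07, with a median above 0 without control replicate 3 or Sema4D replicate 2). Pdgfra (0.86), the fibrillin gene Fbn1 (0.57) and the decorin gene Dcn (0.52) rose. Col1a1, also an osteoblast marker, stood at 4011 ± 159 FPKM in control and 3820.4 ± 89.5 FPKM in Sema4D libraries (limma adjusted p = 0.138, 0.0282 without control replicate 1, range 0.0282 to 0.377). The antimicrobial peptide gene Camp, the only tested neutrophil and erythroid marker, rose and was listed at 0, 0.297 and 0 FPKM in the control libraries and 17.2, 19.2 and 13.1 FPKM in the Sema4D libraries (adjusted p = 1.67e-07). With no filter on low values, 8 genes of that list had a value above 0 in some library, of which 1 rose and none fell (median 0.02). The only tested endothelial marker, Egfl7, fell (-0.30). Of 4 muscle markers, Tnnt3 fell (-0.71), and 3 did not pass, among them Acta1 (adjusted p = 0.10, 0.0152 without Sema4D replicate 3, range 0.0152 to 0.273) and Tnni2 (0.664, 0.00508 without control replicate 1, range 0.00508 to 0.983). Of 2 neural and glial markers, S100b, which cartilage also expresses, fell from 78.2 ± 1.35 to 47.5 ± 1.73 FPKM, and Tubb3 did not pass (adjusted p = 0.105, 0.0133 without control replicate 2, range 0.0133 to 0.271). Of 4 histone genes, Hist1h2bc (-0.33) and Hist1h1c (-0.29) fell, and 2 did not pass, among them Hist1h4i (adjusted p = 0.457, 0.00199 without Sema4D replicate 3, range 0.00199 to 0.905). Of 2 osteoblast markers, Alpl fell and Col1a1 did not pass. Adjusted over the list alone, the counts of these 6 smaller lists were the same.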

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

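Among the 12743 symbols under the expression filter, which entered no test, 7 were listed at 0 in all 3 control libraries and at 0.5 FPKM or more in all 3 Sema4D libraries, a rule set after the data were seen. An exact 0 can be a failed estimate, so no fold is given. Il1b was at 2.14, 1.71 and 1.53 FPKM in the Sema4D libraries (mean 1.79), a cytokine of innate immunity. Calcr was at 1.28, 1.53 and 1.69 FPKM in the Sema4D libraries (mean 1.5), the calcitonin receptor gene. Slc39a4 was at 1.76, 1.24 and 1.47 FPKM in the Sema4D libraries (mean 1.49), a zinc importer gene, and Serpina3f was at 1.18, 1.69 and 0.897 FPKM in the Sema4D libraries (mean 1.26), a serine protease inhibitor gene. Dbx2 was at 1.05, 1.24 and 0.765 FPKM in the Sema4D libraries (mean 1.02), a homeobox gene. Stfa3 was at 0.561, 0.602 and 0.996 FPKM in the Sema4D libraries (mean 0.72), a stefin gene, and Gm12216 was at 0.768, 0.634 and 0.63 FPKM in the Sema4D libraries (mean 0.677), a predicted gene.

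The groups of 3 libraries were not put through a gap test for single outlying values, and with a single contrast no effect can be compared between groups.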

How the results depend on the processing

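One alternative, small RNA genes left out, was chosen after seeing the data, as were the 10 further lists. Over the alternatives and leave-one-out fits, the 133 tested genes eligible by the rule or named for small counts kept direction and side of the threshold in 1953 of their values, lost the call in 10, gained it in 7 and changed sign in 5. Fixed lists did so in 359, 16, 10 and 4, and further lists in 135, 12, 1 and 1. The tally of further lists leaves out the estimated correlation, with which none of them passed camera (lowest adjusted p = 0.0976), and fry, which was not run on them. Counts of calls stayed within 1.5 times the reported ones in 46 cases. The exceptions were treat against 1.5-fold, with 513 genes higher and 199 lower, which asks for a larger change, and the estimated correlation, with 5 lists in place of 16. Leaving out 1 library gave 2471 to 2635 genes higher, 2207 to 2327 lower and 15 to 17 lists. Quantile normalization gave 2167 higher and 3415 lower, shifted the median of all genes to -0.05, and turned 20 of the 5422 calls to the other direction. The hypertrophic list turned up with a mean FPKM of at least 5 (adjusted p = 0.224) and with fry (0.000159). With that mean FPKM, 5 of its 10 members were tested and 2 of them fell. The protease inhibitor list turned down with a mean FPKM of at least 5 (0.811) and without control replicate 2, in a range of 0.932 to 0.98 over the leave-one-out fits, and the ribosomal protein list with quantile normalization (0.0471), for which the cause was not tested. Cd72, not past the threshold in any fit, had a log2 change of -0.0037 with quantile normalization and of -0.030 to 0.064 over the leave-one-out fits, and Tnni2 one of -0.61 to 0.074. With fry, lists that camera did not call passed for protease inhibitors (0.00302), plexins and semaphorins (0.000843), SRF and YAP targets (4.94e-05), cell cycle (0.0325) and fibroblast markers (0.000418). With the replicate number as a block, 2638 genes were higher and 2356 lower, Alpl lost its call (adjusted p = 0.0566), Acta1 gained 1 (0.0373), the oxidative phosphorylation and ribosomal lists lost theirs (0.050), and no other named gene or list changed its call. Same-numbered libraries had correlations of deviations of 0.14, -0.08 and -0.05, and not every library correlated best with its own number. With 3 libraries per group, these values cannot decide whether the numbers pair the libraries. At 1.25e+07 to 1.66e+07 fragments, values under 1 FPKM rest on few fragments in short transcripts.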

Other observations

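The 10 gene lists and the tests on replicate 2, macrophages, scaling and endotoxin were chosen after the data were seen, and the splits of the libraries before. All 16 genes of class I antigen presentation rose with Sema4D (median log2 fold change 1.53, camera adjusted p = 8.66e-12; adjusted p = 0.0976 with an estimated correlation). The loading chaperone gene Tapbp rose from 40 ± 1.75 to 183 ± 6.09 FPKM, the immunoproteasome gene Psmb8 from 0.706 ± 0.0264 to 14.7 ± 3.64 FPKM, the class I heavy chain gene H2-K1 from 11.5 ± 0.509 to 38.4 ± 2.13 FPKM and its light chain gene B2m from 237 ± 3.75 to 445 ± 9.95 FPKM. All 8 guanylate-binding protein genes rose (median 3.21, or 5.07 with a pseudocount of 0.1, adjusted p = 2.63e-08; adjusted p = 0.0976 with an estimated correlation), with Gbp6 going from 0.154 ± 0.0531 to 30.8 ± 2.18 FPKM. Gbp2, Gbp3 and Gbp5 were also on the interferon-stimulated list, so the guanylate-binding protein list is not separate from it. Of 39 proteasome subunit genes, 26 rose and none fell (median 0.13, or 0.07 after quantile normalization, adjusted p = 3.07e-05; adjusted p = 0.149 with an estimated correlation), and after quantile normalization 15 rose and 2 fell. The proteasome and class I lists shared the member with their largest rise (3.18). Of 18 genes of Toll and IL-1 receptor signalling, 11 rose and 1 fell (median 0.76, adjusted p = 1.63e-05; adjusted p = 0.0976 with an estimated correlation), and with no filter on low values 12 of 23 rose (median 0.20). The bacterial lipoprotein receptor gene Tlr2 rose from 8.57 ± 0.201 to 149.8 ± 6.77 FPKM, the endotoxin carrier gene Lbp from 3.92 ± 0.438 to 229 ± 6.79 FPKM and Irak3, a brake on the pathway, from 2.43 ± 0.48 to 22 ± 1.46 FPKM.

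Of 16 genes of zinc and iron handling, 10 rose and 3 fell (median 0.19, camera adjusted p = 0.00181; adjusted p = 0.0976 with an estimated correlation). The ferritin heavy chain gene Fth1, which stores iron, rose from 915 ± 31 to 5247 ± 80.6 FPKM, the iron importer gene Slc11a2 from 12.4 ± 0.295 to 73.6 ± 0.933 FPKM and the zinc and iron importer gene Slc39a14 from 30.2 ± 0.739 to 153 ± 3.75 FPKM, while the iron exporter gene Slc40a1 fell from 18.9 ± 0.575 to 11.4 ± 0.644 FPKM. Of 19 Hox cluster genes, 8 fell and none rose (median -0.20, or -0.38 with a mean FPKM of at least 5, adjusted p = 0.00181; adjusted p = 0.104 with an estimated correlation). Of 77 oxidative phosphorylation genes, 3 rose and 16 fell (adjusted p = 0.0482; adjusted p = 0.15 with an estimated correlation), a call lost in 4 of the leave-one-out fits: without control replicate 2 (0.0555) or 3 (0.0519) and without Sema4D replicate 1 (0.0988) or 2 (0.054). It was also lost with no trend in the variance prior (0.0876) and with a replicate block (0.050), within a range of 0.0010 to 0.0988 over the alternatives with the preset correlation. The 16 falls became 9 without Sema4D replicate 1 and 10 with no trend, and after quantile normalization 1 gene rose and 37 fell. Of 90 ribosomal protein genes, 16 rose and 3 fell (adjusted p = 0.0482; adjusted p = 0.337 with an estimated correlation), and the direction flipped with quantile normalization, where 3 rose and 32 fell. That call was lost without control replicate 3 (0.147) or Sema4D replicate 1 (0.0988), with a mean FPKM of at least 5 (0.0669), median-of-ratios scaling (0.086), no trend (0.0949) or a replicate block (0.050), within a range of 0.0169 to 0.147 over the same alternatives. The 16 rises became 7 without control replicate 3 or with no trend, 10 without Sema4D replicate 1, and 8 without Sema4D replicate 3, with no filter on low values or with a replicate block, and the 3 falls became 1 without Sema4D replicate 2. Of 16 integrin genes 3 rose and 8 fell (adjusted p = 0.0921), while with a mean FPKM of at least 5 none of 8 rose, 6 fell and the list passed (0.00369, within a range of 0.00369 to 0.131 over the same alternatives). Of 21 growth factor receptor genes 7 rose and 7 fell (adjusted p = 0.808).

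The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 2841 genes higher and 2581 lower, and the highest of the other splits gave 1 in either direction. It gave 16 lists past the threshold, and the highest of the other splits 11. Each of the other splits mixed control and Sema4D libraries in both of its groups. The difference between control and Sema4D therefore entered the spread within those groups, which lowers the gene calls, so these splits give no baseline for chance.

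Interferon-stimulated genes were higher in Sema4D replicate 2 than in the other Sema4D libraries (median excess 0.63, SD over the 16 members 0.41). The median excess over all tested genes was 3.60e-05, which argues against scaling or depth as the cause, and that of the NF-kappaB list was -0.03. Of 6 macrophage markers, 4 were highest and 2 lowest in replicate 2 among the Sema4D libraries (median excess 0.088, SD over the members 0.21, highest 0.28). By how much more macrophages would raise these markers was not measured. Values near 1 FPKM are also compressed on this scale, as for Tyrobp at 0.315, 0.846 and 0.746 FPKM in Sema4D replicates 1, 2 and 3. These excesses were smaller than the interferon median, but they cannot exclude macrophages as the cause. No other biological explanation was tested, as the labels give no difference between replicate 2 and the others, and what set replicate 2 apart stays open.

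For the rise of the acute phase, chemokine and NF-kappaB lists, more macrophages in the Sema4D cultures would raise macrophage markers together, but the largest rise among the tested ones was 0.80 (Cd14), and Lyz2, the most abundant of them, fell. Of 15 listed markers 6 were tested, and with no filter on low values 3 of 15 rose and 6 fell (median -0.09). These markers bear on the number of macrophages and do not show which cells made the induced transcripts. Scaling shifted by a few abundant genes would move all genes alike, but the medians of the NF-kappaB, acute phase and chemokine lists exceeded that of all tested genes by 2.37, 4.32 and 4.95 (SD over the members 1.21, 2.96 and 3.20). Camera had already called these lists different from the other genes, so this comparison is no separate test. It does not cover small changes, such as that of Col2a1, which was not past the threshold after quantile normalization. Sema4D itself, acting on cultures that expressed Plxnb1 and Plxnb2, may account for the rise, and so may another stimulant in the protein preparation, such as endotoxin, whose receptor gene Tlr4 was at 7.61 FPKM or more in every control library. These cannot be told apart, since every Sema4D library and no control library received the preparation.

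Small RNA genes, picked out after their values were seen, gave large fold changes with values present in some libraries only. Of 53 tested, 39 were at 0 in a library and above 5 FPKM in another of the same group, against 1 of 11550 other genes. Their median SD within a group was 2.62 on the log2 scale, against 0.10 for other genes of like mean. The cause was not tested. Of these 53 genes, 3 were called higher and 4 lower.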
